A study of Mus musculus with 6 samples.

How the data were processed

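Chromatin accessibility was measured by ATAC-seq, in which the transposase Tn5 inserts sequencing adapters into open DNA, so that reads pile up over accessible stretches of the genome. The cells were NIH3T3, an immortal mouse fibroblast line with an abnormal number of chromosomes. Per the series' design text, stable lines carried an active or an inactive T3H48 hammerhead ribozyme, a self-cleaving RNA, in intron 3 of Actg1, the gene of cytoplasmic gamma-actin. The 6 libraries fell into 2 groups of 3, active ribozyme and inactive ribozyme, by the knock-in label of each sample. The labels do not say whether the 3 libraries of a group came from separate cultures or separately derived lines, so the p-values below measure only the spread between these libraries, which may be technical. All libraries of a group also share the knocked-in construct, and whether they share the history of 1 line is not known, so ribozyme activity and line identity cannot be separated by this design.

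Per the labels' protocols, whole cells were lysed with digitonin and transposed in a single reaction, and the libraries were pooled and sequenced paired-end. Per the submitters' processing notes, the tools included Trimmomatic 0.39, STAR 2.7.11a, Picard 3.1.1, featureCounts and DESeq2 1.36.0, with the mouse genome build mm39. The peak caller, any removal of problematic regions and the way peaks of the libraries were merged are not given in the sources used here. STAR is a splice-aware aligner, and whether reads were shifted for the Tn5 insertion site is likewise not given. A region's value here is a read total over a whole region, for which a shift of a few bases matters little.

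The deposited table listed 52957 regions on 20 chromosomes, the same set for all libraries, with a median width of 447 bp and a range from 148 to 3140 bp. Of these, 19233 (36.3%) carried an annotated gene, by Ensembl gene identifier, up to 5982 bp from a transcription start site, and 13960 carried a gene symbol. The values in the deposited table are a score: reads per region that the authors divided by a size factor for each library and then rounded to whole numbers. This was read from the values themselves. The columns summed to nearly equal totals (6433944 to 6548535), and the median ratio of each library to the geometric mean of all libraries lay between 1.0057 and 1.0063. In addition, 26 whole numbers below 60 never occurred in active replicate 2 and 10 never occurred in active replicate 1, as rounding after multiplication by a factor above 1 gives. The spacing of skipped or overfilled whole numbers gave an estimate of the factor: 1.212, 1.767 and 0.9473 for active replicates 1 to 3 and 0.7178, 0.7712 and 0.8904 for inactive replicates 1 to 3. Dividing by these factors put the reads in regions at about 5340000, 3710000 and 6840000 for the active and 8960000, 8400000 and 7330000 for the inactive libraries. Every active library was thus shallower than every inactive one, and the low regions of the active libraries carry more counting error. Because the values are rounded after scaling, reads were not recovered exactly and no count model was applied.

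Values were analysed as log2(value + 1) with limma 3.58.1 in R 4.3.3 (empirical Bayes with trend and robust settings), with no covariate, over the 51253 regions with a mean of at least 10 across all libraries. The other 1704 regions were not tested. P-values were adjusted by Benjamini-Hochberg over all tested regions, at a threshold of 0.05. Log2 fold changes are on the log2(value + 1) scale, active against inactive, which understates changes of low regions, and bounds of at least 2-fold or 4-fold refer to this scale. Changes given as a fold for a single region are ratios of the group means without the added 1. Tables were read with Python 3.11.15, numpy 2.4.6 and pandas 2.3.3, and plots were drawn with matplotlib 3.10.9. The fit was tested on simulated data with the real region means, the estimated depths and known changes over 51133 simulated regions. It recovered 45 of 99 regions changed 1.5-fold (45.5%) and 92 of 100 changed 2-fold, with 2 false calls. A gene list shifted by 0.3 on the log2 scale was called, and 0 of 13 other lists were. Few regions were changed in the simulation, whereas 60.1% of real regions passed the threshold. The simulated dispersion, the spread beyond counting noise, stood at its lowest allowed value of 0.001. No regional shifts were simulated in the list test. These shares thus need not hold for the real data, and the rate of false list calls there is not known.

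By the original plan, the regions of each actin locus were to be those annotated to the gene or within 50 kb of it. The table held regions annotated to Actb and Acta2, for which this rule was used. For Actg1, Actg2, Acta1 and Actc1, regions annotated to the gene itself are not analysed here. Their locus was taken as the interval between the nearest neighbouring genes that the table holds, by gene order in the GRCm38.p6 annotation, which was used for names and order only. Regions of these intervals can thus lie more than 50 kb from the actin gene. Coordinates are on mm39 as the table lists them. Locus sums were compared by an exact two-sided permutation test over libraries, whose smallest possible p with 3 against 3 is 0.1. Promoter regions were those within 1 kb of a transcription start site, and all others are called distal. Regional shifts were given as the median log2 fold change per chromosome and per 10 Mb window with at least 20 regions.

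The 18 gene lists, the tests and the rule for named genes were fixed before the data were examined. Each gene was represented by its most accessible region within 1 kb of a start site, and 14 lists with at least 3 measured genes were tested with camera at a preset inter-gene correlation of 0.01, adjusted over the lists. Camera with an estimated correlation and fry were run beside it. Fry tests whether the genes of a list move on balance in 1 direction and does not compare them with other genes. The genes named were fixed by rule: all regions of the actin loci, then the 12 higher and 12 lower regions with the largest fold change. Those 24 had to pass the threshold, have non-overlapping groups and lie at or above the median abundance, with 1 region per gene and without genes named only by clone or number, olfactory and vomeronasal receptor genes. From each list up to 4 members past the threshold with the smallest p are named, or 2 with the smallest p where none passed. For the cytoskeleton list only the counts and tests are given, since 1 member that met this rule is not reported here.

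Libraries were compared before use. Between libraries of a group the chi-square per degree of freedom, on the estimated read scale, lay between 1.06 and 1.16, and between 1.11 and 1.56 for regions with a mean of 500 or more. All 6 within-group pairs thus differed slightly beyond counting noise, so no 2 libraries were the same one, and each was entered separately. Values this close to counting noise do not show that the libraries are independent biological replicates. Between groups the value lay between 7.81 and 11.5. Libraries with the same replicate number did not deviate together from their group means, so the numbers do not pair the libraries. Alternatives covered leaving out each library, the replicate number as a block, quantile normalization, no filter on low values, values centred on 10 Mb windows and limma without trend. They also covered other pseudocounts, thresholds, promoter windows and gene summaries, and fry for the lists. Weights from voom on the estimated reads, libraries thinned to the shallowest one, and promoter and distal regions compared within deciles of abundance, were alternatives added after seeing the data. The motif analysis and the correction for GC content were planned and not run, since no genome was used here. The planned surrogate variable was not run either.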

Results

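ATAC-seq profiles were available for 6 libraries of NIH3T3 mouse fibroblasts, 3 with an active and 3 with an inactive T3H48 hammerhead ribozyme knocked into intron 3 of Actg1. By design the active ribozyme is meant to cleave the Actg1 pre-mRNA in which it lies, while the inactive form leaves the transcript whole. Cleavage was not measured here. The series asks whether destabilised RNA sets off transcriptional adaptation, a response in which related genes change their transcription, and the comparison here asks which parts of the genome differ in accessibility between both lines. The 3 active libraries summed to 6477397, 6548535 and 6480023 normalised reads over 52957 regions, and the 3 inactive libraries to 6433944, 6478284 and 6527654. Reads before scaling were estimated at 3710000 to 6840000 in the active and 7330000 to 8960000 in the inactive libraries.

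Regions on the Bahcc1 side of the interval around Actg1, the targeted gene, were less accessible in the active line. Between Bahcc1 and Faap100 on chromosome 11 (120120845 to 120269974 on mm39), the interval that holds Actg1, 10 of 12 regions fell and 0 rose (limma, adjusted p under the threshold of 0.05). All 10 lay from 120120845 to 120153691, no region was analysed from there to 120260590, and the 2 regions on the Faap100 side did not pass. The position of Actg1 within the interval was not used. Whether any of the 10 lies within the planned 50 kb of the gene is thus not known here. Their fall is a result for the Bahcc1 side and not for Actg1 itself. The summed signal of the 12 regions was 2122 ± 18.2 normalised reads in the active and 2824 ± 167 in the inactive libraries (SD, n = 3 each), a log2 ratio of -0.41. The exact permutation test gave p = 0.1, the smallest it can give with 3 against 3. The largest fall in the interval was in a region with no annotated gene at 120141937 to 120142491, from 199.3 ± 22.4 to 105 ± 12.2 (log2 fold change -0.92 ± 0.11 SE, adjusted p = 9.94e-10 by limma).

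The promoter of Bahcc1, 131 bp from its start site, fell from 266 ± 19.1 to 192 ± 1 normalised reads (log2 fold change -0.47, adjusted p = 6.06e-06 by limma, n = 3 per group). The most accessible region of the interval, at 120147233 to 120148251, fell from 700.7 ± 41.2 to 589 ± 23.4. The promoter of Faap100 was at 199 ± 1.73 in the active and 224.7 ± 16 in the inactive libraries and did not pass the threshold (adjusted p = 0.0767 by limma). The region at 120260590 to 120260919 did not pass either (23.7 ± 6.66 against 30 ± 2, adjusted p = 0.177 by limma). With quantile normalization this region was called lower (log2 fold change -0.56, adjusted p = 0.0371 by limma). Regions annotated to Actg1 itself, including its promoter, were not analysed here, so that the locus sum stands for flanking regions alone. The surroundings also fell: the median log2 fold change of the 80 regions in the window from 120 to 130 Mb, these 12 included, was -0.39. In the window from 110 to 120 Mb the median was -0.26. Centred on the median of its own window, the log2 ratio of the locus sum was -0.02 (exact permutation p = 0.7). With centred values 2 of the 12 regions were lower, among them that at 120141937 (-0.53), and 2 were higher, the Faap100 promoter (0.22, adjusted p = 0.0213 by limma) and the region at 120147233 (0.14, adjusted p = 0.0256 by limma), while the Bahcc1 promoter lost its call (-0.07). A Bahcc1 region at 120121983 lost its call without active replicate 3 (-0.23), inactive replicate 1 (-0.30) or inactive replicate 3 (-0.20). In limma without trend the calls at 120147233 (adjusted p = 0.0586) and 120121983 (adjusted p = 0.0761) were lost, and with libraries thinned to equal depth those at 120121983 (-0.29) and 120131818 (-0.39).

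Around Actg2, the gene of smooth muscle gamma-actin and a paralogue of the targeted gene, 3 of 4 regions fell and 0 rose. The interval ran from Dguok to Stambp on chromosome 6 (83483404 to 83549816), and its sum was 550.7 ± 42.3 in the active and 689.7 ± 23.6 in the inactive libraries. The log2 ratio was -0.32 (exact permutation p = 0.1, the smallest possible). The Dguok promoter, for a mitochondrial nucleoside kinase, fell from 489.7 ± 5.86 to 386 ± 30.3 (log2 fold change -0.35, adjusted p = 1.51e-05 by limma), and that of Stambp, a deubiquitinase, from 165 ± 10.1 to 137.3 ± 25.6 (adjusted p = 0.0266 by limma).

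The 2 regions without an annotated gene between both promoters were low. The region at 83518955 to 83519280 fell from 20 ± 4 to 11 ± 3.61 normalised reads (log2 fold change -0.84 ± 0.32 SE, adjusted p = 0.0215 by limma). The region at 83489498 to 83489722 was at 16.3 ± 0.577 in the active and 15 ± 4.36 in the inactive libraries (log2 fold change 0.15 ± 0.30 SE, adjusted p = 0.686 by limma). The latter values overlapped between the groups, and regions annotated to Actg2 itself were not analysed here. The Stambp call was lost without active replicate 1 (log2 fold change -0.15), active replicate 3 (-0.27), inactive replicate 2 (-0.24) or inactive replicate 3 (-0.27), and the call at 83518955 without active replicate 1 (-0.57), inactive replicate 2 (-0.70) or inactive replicate 3 (-0.83). The Stambp call was also lost in limma without trend (adjusted p = 0.166) and the call at 83518955 with libraries thinned (-0.59). Centred on the window, whose median was -0.10, the Actg2 locus stayed at a log2 ratio of -0.22 (exact permutation p = 0.1), with 0 regions higher, 2 lower, the Dguok promoter at -0.24 and the Stambp promoter at -0.18, which no longer passed.

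The other actin loci went in different directions. At Actb, the gene of cytoplasmic beta-actin on chromosome 5 (142888870 to 142892509), the promoter stood at 754 ± 75.1 in the active and 765.7 ± 4.04 in the inactive libraries and did not pass the threshold (log2 fold change -0.03 ± 0.05 SE, adjusted p = 0.691 by limma). Within 50 kb of the gene, 6 of 12 regions rose and 0 fell, among them a further Actb region 3230 bp from the start site (51 ± 5.29 to 81.7 ± 19.9, log2 fold change 0.64). The strongest was a region at 142898613 to 142898839 that rose from 22 ± 5 to 72 ± 21.2 (log2 fold change 1.64, adjusted p = 1.11e-08 by limma). The locus sum rose to 2393 ± 52.8 from 2107 ± 53.4 (log2 ratio 0.18, exact permutation p = 0.1).

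At Acta2, the gene of smooth muscle alpha-actin on chromosome 19 (34218490 to 34232990), 7 of 10 regions fell and 0 rose. The Acta2 promoter fell from 323 ± 20.7 to 264 ± 10 (log2 fold change -0.29 ± 0.07 SE, adjusted p = 9.75e-04 by limma), the Fas promoter from 305.7 ± 13.7 to 243 ± 3.46, and the locus sum from 1571 ± 20.1 to 1267 ± 59.9 (log2 ratio -0.31, exact permutation p = 0.1). At Acta1, the skeletal muscle actin gene, whose interval between Ccsap and Nup133 lies on chromosome 8, 1 of 8 regions rose and 2 fell. The region that rose, at 124609985 to 124610600, went from 54 ± 6.08 to 161 ± 9.54 (log2 fold change 1.56, adjusted p = 5.48e-14 by limma), and the sum had a log2 ratio of 0.11 (exact permutation p = 0.1). The median log2 fold change of the 8 regions was -0.05, which differed in sign from the sum.

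At Actc1, the cardiac muscle actin gene, in the interval between Arhgap11a and Zfp770 on chromosome 2, 1 of 5 regions rose and 3 fell. The sum was 702.7 ± 76.1 in the active and 780.7 ± 37.1 in the inactive libraries, which differed by less than the spread between libraries can show (log2 ratio -0.15, exact permutation p = 0.3). Centred on its 10 Mb window, Actb turned to a log2 ratio of -0.15 (exact permutation p = 0.1), while Acta1 stood at 0.29 (p = 0.1). Acta2 went to 0.02 (exact permutation p = 0.6) and Actc1 to 0.03 (p = 0.9), a change of sign with values near 0. With centred values 1 region was higher and 2 lower at Actb, 2 and 2 at Acta2, 3 and 1 at Acta1, and 2 and 1 at Actc1. The centred Actb promoter was lower (-0.36, adjusted p = 3.35e-06 by limma), whereas the Actb region 3230 bp from the start site (0.31), the Acta2 promoter (0.04) and the Fas promoter lost their calls.

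Of the 33 actin locus regions past the threshold, 9 lost their call when 1 library was left out, of which 3 lay at Actg1 and Actg2. Near Actb the region at 142921469 did so without any library but active replicate 2, with a log2 fold change of 0.28 without active replicate 1. Near Acta2 both Stambpl1 regions did so without active replicate 1 (-0.14 and -0.22), and 1 of them also without inactive replicate 3 (-0.16). Near Actc1 the region at 113925053 did so without any library but active replicate 2 (0.19 without active replicate 1) and Arhgap11a without active replicates 2 or 3 and inactive replicates 1 or 3 (-0.14 without inactive replicate 3). Zfp770 did so without active replicate 2 (-0.25) or inactive replicate 3 (-0.40). In limma without trend the same 6 regions near Actb, Acta2 and Actc1 lost their calls. The regions at 142921469 (0.26) and 113925053 (0.37) and 1 Stambpl1 region (-0.34) did so with libraries thinned, and those at 142921469 (0.32) and 113925053 (0.24), Arhgap11a (-0.13) and the Stambpl1 promoter (-0.16) with quantile normalization.

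**Figure D1:**
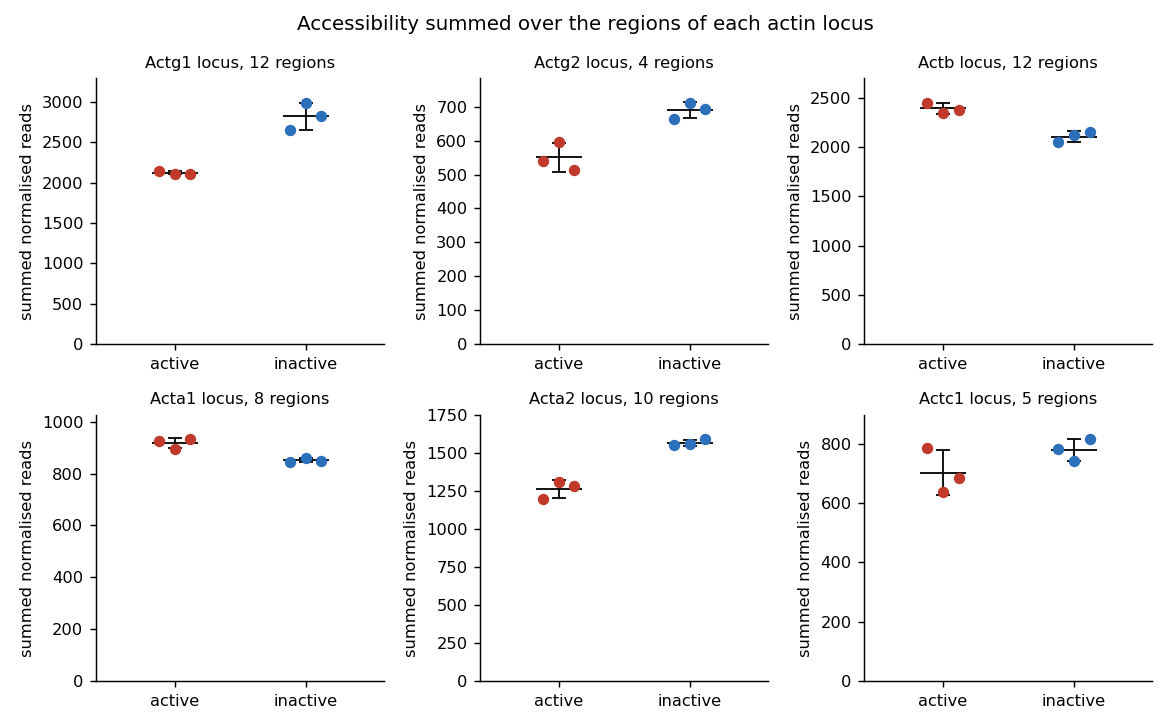
Normalised reads per library (vertical axis, from 0) summed over the regions of each actin locus in the 3 active (red) and 3 inactive (blue) libraries, with the mean and SD as bars. The groups do not overlap at Actg1, Actg2, Actb, Acta1 and Acta2, where the log2 ratios of the means are -0.41, -0.32, 0.18, 0.11 and -0.31.

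Across the genome, accessibility differed widely between the lines. Of 51253 regions tested, 15827 (30.9%) were higher in the active line, 14957 (29.2%) were lower and 20469 did not pass the threshold (limma, adjusted p under 0.05). Changes of at least 2-fold numbered 10375, of which 6861 were higher and 3514 lower, and changes of at least 4-fold numbered 2318 higher and 627 lower. The 3 active libraries lay wholly above or below the 3 inactive ones in 62.3% of regions, where chance gives 10%. The median log2 fold change over all regions was -0.02, and the 5th and 95th percentiles were -1.17 and 1.90.

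Libraries of a group resembled each other far more than those of the other group. Pearson correlations across regions, which are not independent replicates, were 0.969 to 0.976 among active libraries, 0.982 to 0.984 among inactive libraries and 0.821 to 0.829 between groups. The first principal component held 84.7% of the variance and separated active from inactive libraries.

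Among regions at or above the median abundance, the 12 higher and 12 lower ones near different named genes with the largest fold change were picked by a rule fixed beforehand. Less abundant regions, which this rule leaves out, had larger changes in both directions. Marchf3, which encodes a membrane-bound ubiquitin ligase, rose at its promoter (chromosome 18, 57058330 to 57059085) from 21.3 ± 2.52 to 259.7 ± 12.9 normalised reads, 12.2-fold (log2 fold change 3.55 ± 0.14 SE, adjusted p = 8.18e-24 by limma, n = 3 per group). Slc2a13, a myo-inositol transporter, rose at its promoter on chromosome 15 (91456859 to 91457769) from 19.3 ± 0.577 to 219 ± 17.4, 11.3-fold. Baiap2l1, an adaptor that links membranes to the actin skeleton, rose at its promoter on chromosome 5 (144294656 to 144295559) from 68.7 ± 6.35 to 622.3 ± 29.9, 9.06-fold. The promoter of Mboat2, a lysophospholipid acyltransferase, rose 7.58-fold, that of Tspan12, a tetraspanin of the Norrin receptor, 5.72-fold, and that of Sh2b2, an adaptor of insulin signalling, 4.52-fold.

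Regions farther from the start site rose at Dsg2, a cadherin of desmosomes (6.59-fold, 3606 bp from the start site), and Angpt4, an angiopoietin (6.46-fold, 3071 bp). They also rose at Eif4e, the cap-binding translation factor (4.44-fold, 5079 bp), Erlin2, a protein of the endoplasmic reticulum (4.15-fold, 2357 bp), Def8 (4.07-fold, 3965 bp) and the antisense RNA gene Tnk2os (4.08-fold, 4310 bp). The Def8 region on chromosome 8 (124152957 to 124155505) was the most accessible of the 12, at 1744 ± 112 in the active and 428.7 ± 23.0 in the inactive libraries. All 3 Angpt4 regions in the table rose, whereas 1 of 2 Eif4e regions, 1 of 2 Erlin2 regions and 1 of 2 Def8 regions did.

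The 12 losses picked in the same way were smaller. Olfml2b, which encodes a secreted olfactomedin-like protein, fell at its promoter on chromosome 1 (170471738 to 170472375) from 384 ± 15.5 to 70.3 ± 11.7, 5.46-fold (log2 fold change -2.44 ± 0.10 SE, adjusted p = 8.58e-23 by limma). The promoters of Tmem204, a membrane protein, fell 4.05-fold, of Acat1, a mitochondrial thiolase of ketone body metabolism, 3.95-fold, and of Tdrp 3.75-fold. Those of Pfkfb3, a kinase that stimulates glycolysis, fell 3.73-fold, of Ptgs1, a cyclooxygenase of prostaglandin synthesis, 3.64-fold, and of Dlec1 3.36-fold.

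Away from the start site by more than 1 kb, regions fell at Mlph, a melanosome transport protein (3.9-fold), Serpinf1, a secreted anti-angiogenic serpin (3.49-fold), Camk2a, a calmodulin-dependent kinase (3.44-fold), and Odf3l1 (3.29-fold). A region 433 bp from the T cell receptor segment Trav6-7-dv9 fell 3.44-fold. The active level of these 12 regions ranged from 31.7 ± 12.2 at Ptgs1 to 101 ± 13.9 at Pfkfb3. All 24 kept their call and direction under each of the 15 alternatives run for them, the values centred on windows included, which moved the log2 fold change of Tspan12 from 2.50 to 1.39, of Acat1 from -1.96 to -1.19 and of Odf3l1 from -1.72 to -0.94.

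**Figure D2:**
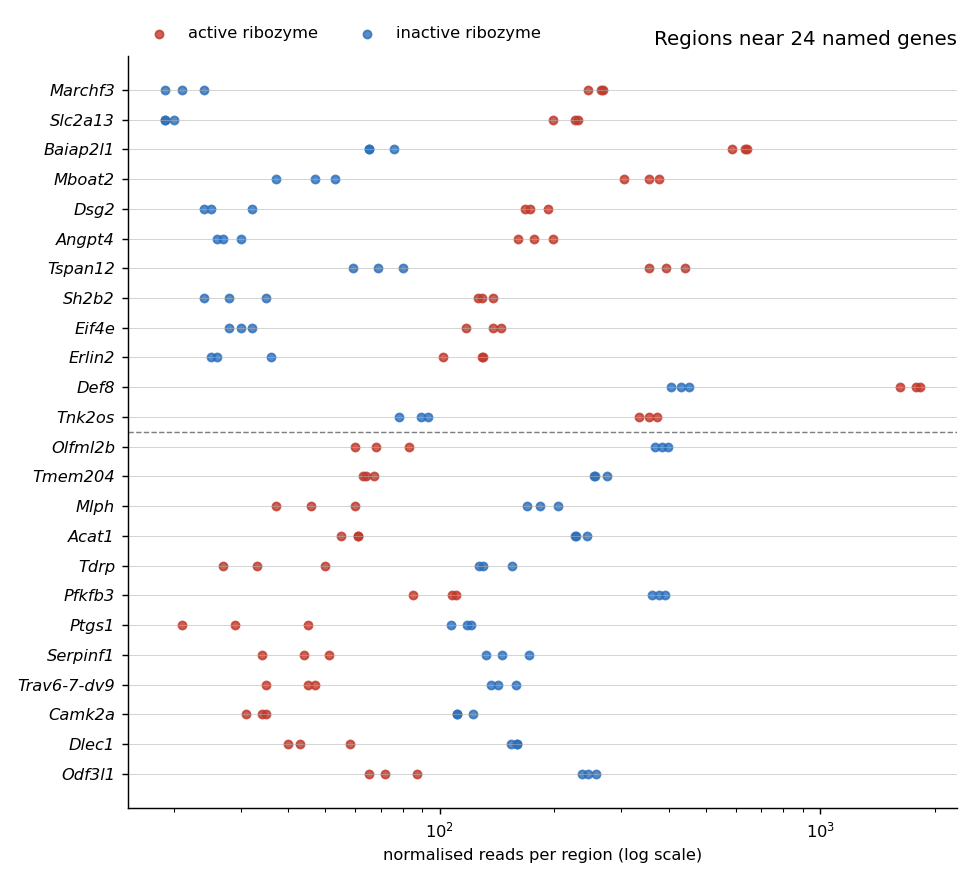
Normalised reads per region (horizontal axis, log scale) for the 24 named genes in each of the 3 active (red) and 3 inactive (blue) libraries, with 12 higher genes above the dashed line and 12 lower genes below it. In every row the groups are apart, from Marchf3 at the top (12.2-fold higher) to Odf3l1 (3.29-fold lower).

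Promoters and distal regions differed in the direction of their changes and in how far they changed. Of 11143 promoter regions, 22.4% were higher and 36.6% lower, against 33.2% and 27.1% of 40110 distal regions. The odds of being higher were lower for promoters (odds ratio 0.578, two-sided Fisher exact test, p = 5.97e-112), and the odds of being lower were raised (1.55, p = 1.27e-82), in tests that treat regions as independent. Distal regions also changed farther: 23.9% of them passed the threshold with at least a 2-fold change, against 6.91% of promoter regions. These 2-fold shares were not compared within deciles of abundance. The smaller share of promoters among gains held under all alternatives run. The larger share among losses did not: the difference of 9.52 percentage points went to -1.50 with values centred on windows and to -0.58 for limma without trend.

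The direction of calls also followed abundance. In the lowest decile of mean abundance 40.8% of regions were higher and 24.9% lower, and in the highest decile 25.05% and 40.5%. Promoters were more abundant than distal regions, with 3603 of the 5126 regions in the highest decile. Compared within deciles, an alternative chosen after seeing the data, promoter minus distal shares differed by -7.34 points for higher regions. For lower regions the difference shrank to 2.54 points.

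The changes followed chromosomes. Regions on chromosome 12 were shifted up, with a median log2 fold change of 0.50 and 67.2% of 1798 regions higher, followed by chromosomes 13 (0.33), 6 (0.31), 5 (0.29) and 15 (0.27). Chromosome 18 was shifted down, with a median of -0.38 and 53.1% of 1736 regions lower, followed by chromosomes 9 (-0.29), 11 (-0.25), 19 (-0.24) and 2 (-0.18). The median of chromosome 12 was 0.50, 0.52 and 0.52 in the 3 active libraries taken one at a time against the mean of the inactive ones, and that of chromosome 18 was -0.38, -0.34 and -0.36.

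Within chromosomes the shifts varied between windows, and no borders were located. The first 30 Mb of chromosome 6 held medians of 1.02, 0.94 and 1.12 per 10 Mb window, and in the window from 20 to 30 Mb 88.4% of 129 regions were higher. From 30 to 70 Mb the window medians of the same chromosome were 0.79, 0.43, 0.32 and 0.49. Its window from 130 to 140 Mb stood at -0.55. The first 60 Mb of chromosome 9 lay between -0.78 and -0.53, with 81.6% of 185 regions lower between 20 and 30 Mb. The windows at 110 to 120 Mb of chromosome 14 (1.04), 80 to 90 Mb of chromosome 5 (0.89) and 20 to 30 Mb of chromosome 12 (0.87) were also high.

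Over 268 windows the medians had an SD of 0.29, with 46 windows above 0.3 and 20 below -0.3. The windows accounted for 11.04% of the variance of fold changes among regions. A read total per region cannot tell the number of DNA copies from the accessibility of each copy. With values centred on windows, 14126 regions were higher and 11465 lower, and 21511 of the 30784 regions called before kept their call and direction.

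**Figure D3:**
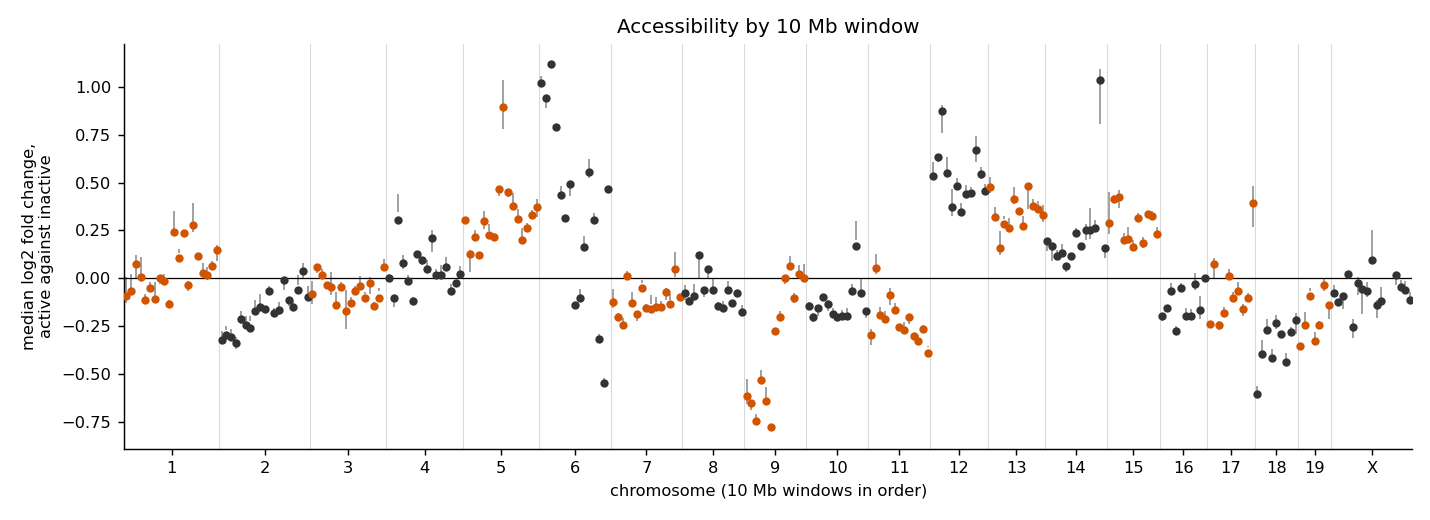
Median log2 fold change, active against inactive (vertical axis), of the regions in each of 268 windows of 10 Mb, in order along the chromosomes (horizontal axis, colours alternate by chromosome). Points are medians and grey lines span the 3 active libraries taken one at a time against the inactive mean; the window at 20 to 30 Mb of chromosome 6 is highest at 1.12 and that at 50 to 60 Mb of chromosome 9 is lowest at -0.78.

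Promoters of 9416 genes could be set against the gene lists, of which 1995 (21.2%) were higher, 3548 (37.7%) lower and 3873 not past the threshold, with a median log2 fold change of -0.11. None of the 14 lists tested passed camera after adjustment (lowest adjusted p = 0.164), and 2 had an unadjusted p under 0.05, both in the lower direction: fibroblast extracellular matrix genes and immediate early genes. With an estimated correlation the adjusted p was 0.725 for every list. Fry, which does not compare a list with other genes, called 1 list higher and 8 lower. With values centred on windows camera called 2 lists lower, the same extracellular matrix (adjusted p = 0.0377) and immediate early genes (adjusted p = 0.0132). These 2 calls rest on the preset correlation of 0.01, since the estimated correlation was not run with centred values. Without centring it was 0.116 for immediate early genes.

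Fibroblast extracellular matrix genes were mostly lower, with 15 of 22 promoters lower, 3 higher and the same counts adjusted over the list alone (median log2 fold change -0.27, camera p = 0.015, p = 0.0628 with an estimated correlation, fry adjusted p = 0.00119). Loxl1, an enzyme that crosslinks elastin, fell 3.04-fold from 261.7 ± 9.87 to 86 ± 11.53, within the chromosome 9 window whose median was -0.78. Lox, which crosslinks collagen, fell 1.51-fold, Pdgfrb, a receptor of platelet-derived growth factor, 1.67-fold and Col4a2, a basement membrane collagen, 1.64-fold. Centred on their windows, the log2 fold changes shrank from -1.60 to -0.82 at Loxl1, -0.59 to -0.30 at Lox and -0.75 to -0.31 at Pdgfrb.

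Immediate early genes, which respond to serum and growth factors, were also mostly lower, with 14 of 23 promoters lower and 3 higher, likewise adjusted over the list alone (median -0.19, camera p = 0.0235, p = 0.254 with an estimated correlation, fry adjusted p = 0.00595). The promoters of Ier2 fell 1.84-fold (430 ± 25.2 to 234 ± 15.7), Klf2 1.54-fold, Egr1 1.32-fold and Jund 1.28-fold. Egr1 lay in a window with a median of -0.41, and centred on it its log2 fold change was 0.02, while that of Jund shrank from -0.36 to -0.21.

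Genes that serum response factor and its actin-regulated coactivators MRTF control went both ways, with 11 of 27 promoters higher and 8 lower, or 11 and 9 adjusted over the list alone (median 0.04, camera p = 0.0727 in the higher direction, p = 0.256 with an estimated correlation, fry adjusted p = 0.0671). Tes, a focal adhesion protein, rose 2.47-fold (87.7 ± 10.2 to 216.3 ± 11.2), Lmod1, an actin filament nucleator, 2.15-fold, Zyx, a zyxin of focal adhesions, 1.32-fold and Actn1, an alpha-actinin, 1.28-fold. Tes lay in a chromosome 6 window with a median of 0.94, and centred on it its log2 fold change shrank from 1.30 to 0.36. Smooth muscle contractile genes had 4 of 11 promoters higher and 3 lower, likewise adjusted over the list alone (camera p = 0.331, p = 0.365 with an estimated correlation). Their median of -0.06 and mean of 0.21 differed in sign, and camera and fry pointed to the higher side (fry adjusted p = 0.0208). Mylk, the myosin light chain kinase, rose from 7 ± 1 to 36.3 ± 18.1 and Cald1, caldesmon, 1.23-fold, while Tagln, transgelin, fell 1.365-fold.

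Among 8 actin-related genes 2 were higher and 2 lower, likewise adjusted over the list alone (camera p = 0.405, p = 0.662 with an estimated correlation, fry adjusted p = 0.19). The median of -0.01 differed in sign from the mean of 0.23 and the direction of the test. Actr3b, a subunit of the actin-nucleating Arp complex, rose 3.97-fold from 10.3 ± 1.53 to 41 ± 7 and Actr10, of the dynactin complex, 1.46-fold, while Actr1a, also of dynactin, fell 1.29-fold and Actr2 1.13-fold. The Actr2 call was lost without active replicate 1 (log2 fold change -0.14) or inactive replicate 3 (-0.15). Of the actin isoforms 2 were measured, and Acta2 fell while Actb did not pass, likewise adjusted over the list alone. Cytoskeleton regulators had 9 of 35 promoters higher and 9 lower, likewise adjusted over the list alone (camera p = 0.225, p = 0.46 with an estimated correlation, fry adjusted p = 0.351). Their median of -0.08 differed in sign from the mean of 0.01 and the test.

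Lists tied to RNA decay and to histone modification, which the study's topic brings up, did not pass camera, which compares them with other genes, and 37.7% of all gene promoters were lower. Of 24 RNA decay genes 6 were lower and 1 higher, or 5 and 1 adjusted over the list alone (median -0.12, camera p = 0.559, p = 0.706 with an estimated correlation, fry adjusted p = 0.0192), with falls of 1.46-fold at Exosc2, 1.18-fold at Exosc6 and 1.16-fold at Exosc8, all of the RNA exosome, and 1.22-fold at Lsm4. The Exosc8 call was lost without active replicate 1 (log2 fold change -0.13). Of 17 genes of the COMPASS and WDR5 complexes, 7 were lower and 3 higher, likewise adjusted over the list alone (median -0.12, camera p = 0.32, p = 0.453 with an estimated correlation, fry adjusted p = 0.0113). The Kmt2a promoter fell 1.56-fold, in a window with a median of -0.64, Hcfc1 1.39-fold, Men1 1.359-fold and Cxxc1 1.25-fold.

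Growth and stress lists did not pass camera either. Of 31 cell cycle genes 10 were lower and 4 higher, likewise adjusted over the list alone (median -0.09, camera p = 0.527, p = 0.578 with an estimated correlation, fry adjusted p = 0.0106). Ccnd2, a cyclin, fell 1.73-fold, Cdkn1b, a cyclin-dependent kinase inhibitor, 1.7-fold, Top2a, a topoisomerase, 1.48-fold and Aurkb, a mitotic kinase, 1.29-fold. Centred on windows, Cdkn1b shrank from -0.76 to -0.21 on the log2 scale, Ccnd2 from -0.79 to -0.47 and Top2a from -0.56 to -0.26. Of 21 p53 targets 10 were lower and 3 higher, likewise adjusted over the list alone (median -0.07, camera p = 0.617, p = 0.684 with an estimated correlation, fry adjusted p = 0.0165), where Eda2r fell 1.92-fold, Ccng1 1.28-fold and Phlda3 1.25-fold, while Rrm2b, a ribonucleotide reductase subunit, rose 1.39-fold (log2 fold change 0.48, centred 0.28). Of 27 ribosomal protein genes 13 were lower and 3 higher, or 15 and 3 adjusted over the list alone (median -0.19, camera p = 0.198, p = 0.466 with an estimated correlation, fry adjusted p = 0.0146). Rpl10 fell 1.358-fold, Rpl27 1.34-fold, Rpl23 1.41-fold and Rps15 1.38-fold (log2 fold change -0.46, centred -0.27).

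Of 17 YAP and TEAD targets 5 were lower and 0 higher, likewise adjusted over the list alone (median -0.12, camera p = 0.448, p = 0.58 with an estimated correlation, fry adjusted p = 0.0192). Birc5, an apoptosis inhibitor, fell 1.364-fold (log2 fold change -0.45, centred -0.18), Ccn1, a matricellular protein, 1.26-fold, Myof, myoferlin, 1.28-fold and Crim1 1.12-fold. The Crim1 call was lost without active replicate 1 (log2 fold change -0.12) or inactive replicate 3 (-0.14). Of 16 interferon-stimulated genes 3 were higher and 4 lower, likewise adjusted over the list alone (camera p = 0.674, p = 0.725 with an estimated correlation, fry adjusted p = 0.811). The median of -0.05 lay below 0 while camera pointed to the higher side. Usp18 rose 1.49-fold (log2 fold change 0.57, centred 0.89) and Cxcl10 1.39-fold, while Ifit2 fell 1.46-fold (log2 fold change -0.55, centred -0.22) and B2m 1.22-fold.

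Markers of other cell types were mostly not measured at promoters. Of 15 epithelial markers 4 were measured and Krt8, a keratin of simple epithelia, rose 1.73-fold from 85 ± 6.08 to 147 ± 20.8, with 1 higher and 0 lower, likewise adjusted over the list alone (median 0.03, camera p = 0.292, p = 0.41 with an estimated correlation, fry adjusted p = 0.216). Of 15 neuronal and pluripotent markers 2 were measured and both were lower, likewise adjusted over the list alone, Tubb3 1.39-fold (log2 fold change -0.48, centred -0.30) and Map2 1.26-fold. Of 21 skeletal and cardiac muscle markers only Ckm was measured, at 28 ± 5 in the active and 32.3 ± 2.52 in the inactive libraries, and it did not pass, likewise adjusted over the list alone. Of 14 hematopoietic markers 0 were measured.

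With values centred on windows, Acta2, Egr1, Zyx, Actn1, Cald1, Tagln, Actr2 and Kmt2a, and the mean of the cytoskeleton list against other genes, changed sign. Of these genes only Cald1 passed the threshold in the new direction (-0.49, adjusted p = 4.08e-06 by limma). Of the 56 list members that met the rule for naming, 17 others lost their call under that setting and kept their direction, among them all 4 named RNA decay genes (Lsm4, Exosc2, Exosc6 and Exosc8), Men1, Cxxc1, Actr10, Actr1a, Myof, Crim1, Cxcl10, B2m, Aurkb, Rpl27, Rpl23 and Map2. Myof (-0.02) and Crim1 (-0.0048) came close to 0. In limma without trend Actr2, Crim1, Lsm4, Exosc8 and Map2 lost their calls, and with libraries thinned Myof did (-0.23), while Cxxc1 shrank from -0.33 to -0.21.

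**Figure D4:**
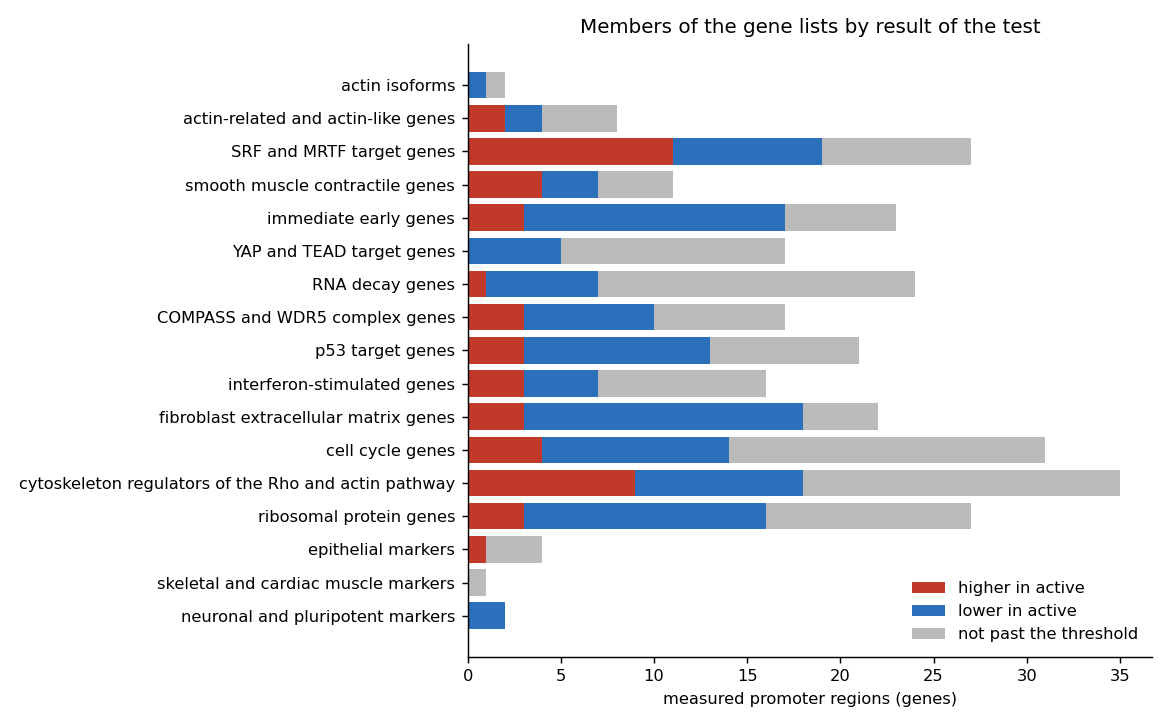
Number of measured promoter regions (horizontal axis, 1 per gene) of each gene list that were higher (red), lower (blue) or not past the threshold (grey) in the active against the inactive line. Extracellular matrix genes (15 of 22 lower) and immediate early genes (14 of 23 lower) hold the largest shares of lower members among lists with more than 2 measured genes; 17 of the 18 lists are drawn, since 0 hematopoietic markers were measured.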

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

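Weights from voom, libraries thinned to equal depth and promoters matched on abundance were chosen after seeing the data, and the other alternatives before. The counts of regions kept within 1.5 times of 15827 higher and 14957 lower under each alternative except a minimum log2 fold change of 1, which by its construction left 6861 and 3514. Leaving out 1 library gave 14585 to 15556 higher and 12774 to 14689 lower regions. Depth limits the low regions of the shallower active libraries: with all libraries thinned, 24979 of the 30784 calls stayed past the threshold in the same direction, 5805 no longer passed and 0 were called the other way by limma.

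Replicate numbers do not pair the libraries (correlations of deviations 0.0014, -0.0060 and -0.016), and with the replicate number as a block 15749 regions were higher and 14858 lower.

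Without 1 library the locus log2 ratios ranged from -0.45 to -0.37 at Actg1, -0.39 to -0.28 at Actg2, 0.16 to 0.20 at Actb, 0.10 to 0.13 at Acta1, -0.34 to -0.27 at Acta2 and -0.24 to -0.09 at Actc1. The promoter minus distal share ranged from -11.8 to -9.50 points for higher and 6.18 to 10.97 for lower regions, and the SD of window medians from 0.293 to 0.296. Median correlations ranged from 0.974 to 0.982 within and 0.824 to 0.827 between groups, with 0 lists called in either direction.

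Centred on 10 Mb windows, the locus ratios changed sign at Actb (-0.15), Acta2 (0.020, exact permutation p = 0.6) and Actc1 (0.031, exact permutation p = 0.9). The promoter minus distal share of lower regions went to -1.50 points there (Fisher exact p = 7.61e-04) and to -0.58 in limma without trend (p = 0.205). For centred values the reversal follows from subtracting the window medians, and elsewhere the cause was not tested. The cytoskeleton list mean went to -0.018, and members reversed at Acta2 (0.040), Actr2 (0.015), Zyx (-0.036), Actn1 (-0.089), Tagln (0.20), Cald1 (-0.49, adjusted p = 4.08e-06 by limma), Egr1 (0.015), Kmt2a (0.0024) and Wasl (-0.19, adjusted p = 0.0147 by limma). Locus regions reversed at Bahcc1 (0.11), 120147233 (0.14), 120260590 (0.024), Faap100 (0.22), D430018E03Rik (-0.27), Fbxl18 (-0.070), 142906294 (-0.011), 142918021 (-0.30), 124611433 (0.11), Nup133 (0.14) and Stambpl1 (0.11). Camera called 2 lists lower with centred values at the preset correlation, the only one run there, and fry without centring called 1 higher and 8 lower.

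Quantile normalization reversed the mean of interferon-stimulated genes (-0.020) and the regions at 83489498 (-0.12), 142914623 (0.025) and 142918021 (-0.061). Thinning reversed the regions at 142840739 (0.038) and 142918021 (-0.014). Single regions that reversed without 1 library had not passed the threshold: they ranged from -0.13 to 0.011 at 142840739, -0.011 to 0.14 at D430018E03Rik, -0.11 to 0.023 at the Actb promoter, -0.061 to 0.0027 at 142914623, -0.029 to 0.070 at 142918021, -0.12 to 0.023 at 124611433 and -0.12 to 0.032 at Nup133. The cause was not tested.

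The median correlation between groups, 0.826, moved to 0.842 with centring, 0.817 and 0.859 with pseudocounts of 0.5 and 5, 0.815 with voom weights and 0.810 with thinning. That within groups moved from 0.979 to 0.963 with thinning, and the SD of window medians from 0.295 to 0.277 with a pseudocount of 5. The GC correction, motif windows and the surrogate variable were not run, and the SD of window medians has no value with centring, which sets it to 0.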

Other observations

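The tests in this part were chosen only after the result was seen, except the 2 comparisons with other splits of the libraries and the planned setting with values centred on 10 Mb windows, whose use as a test of a cause was chosen afterwards. Stretches of neighbouring regions that differed together were picked after their values were seen, as runs of at least 5 consecutive regions that each differed at least 4-fold in 1 direction. No limit was set on the distance between neighbours, and the run annotated to Cdh12 held 10 regions over 7956 kb. There were 64 such runs with 411 regions, of which 13 runs were low in the active line and 51 low in the inactive line. At Sash1, which encodes a signalling scaffold protein, 11 regions on chromosome 10 (8636363 to 8845657) summed to 39.7 ± 4.16 normalised reads in the active and 779.3 ± 9.29 in the inactive libraries (SD, n = 3 each). Other runs low in the active line lay at Pcdh9, a protocadherin (15 ± 2.65 against 349.3 ± 4.62), at the Trim12c and Trim30 gene cluster (21.3 ± 2.08 against 365.3 ± 37.9), at Sod3, the extracellular superoxide dismutase (23.7 ± 8.33 against 396.3 ± 24.1), and at Nnmt, a nicotinamide methyltransferase (83.7 ± 3.21 against 646.3 ± 4.16).

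Runs low in the inactive line included Fmn1, a formin that nucleates actin filaments, with 12 regions on chromosome 2 (112848368 to 113158315) that summed to 954.7 ± 10.97 in the active and 102.7 ± 14.3 in the inactive libraries. The run named after Pard3b, a cell polarity gene, held 11 regions over 668.3 kb (682.3 ± 34.1 against 54.3 ± 2.08). That named after Calcb, a calcitonin-related peptide gene, held 11 over 297.6 kb (993.7 ± 26.9 against 163 ± 11.4). That of the Serpina3b and Serpina3h cluster held 7 over 147.8 kb (389 ± 14.2 against 20 ± 1). The runs given here are named after any gene to which 1 of their regions was annotated, and the other regions need not belong to that gene. Most runs held no region with a gene symbol. Only 28 of the 411 regions were promoters.

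Accessibility shifted over whole chromosomes and 10 Mb windows. A single scaling factor per library would move all windows alike, but the highest and lowest window medians differed by 1.90 on the log2 scale, and with libraries thinned to equal depth the SD of the medians was 0.298, which argues against the lower depth of the active libraries. A difference in DNA copy number as the whole cause was predicted to move promoters and distal regions of a window alike. The slope of promoter on distal medians was 0.794 (bootstrap interval 0.721 to 0.861). It was not matched on abundance, which was higher for promoters and went with fold change: the median log2 fold change was 0.21 in the lowest and -0.08 in the highest decile. The slope thus cannot decide. Promoter and distal medians correlated at 0.933 across windows, so a copy number difference stays open as the whole or part of the cause, and a regional change of chromatin remains open beside it.

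The share of regions past the threshold was 60.1%. Shifts of whole 10 Mb windows alone and the lower depth are argued against as whole causes, since 69.9% of the calls stayed past the threshold in the same direction with values centred on windows (364 were called the other way) and 81.1% with libraries thinned. Centring subtracts 1 median per window, so it cannot decide on shifts over shorter stretches or with borders inside a window. A difference between the lines other than ribozyme activity stays open as a candidate explanation: libraries of a group differed by a chi-square per degree of freedom of at most 1.16 over all regions and 1.56 over regions with a mean of 500 or more, and the labels name no separately derived lines. The 10 splits of the 6 libraries are too few for a share under 0.05: the real split called 30784 regions, the highest other split called 0, and 1 split, the real one itself, reached this number. For lists with an unadjusted camera p under 0.05 they are likewise too few, with 2 lists in the real split, 3 in the highest other and 5 splits with as many or more, the real one included.

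The runs are not neighbours by chance in scattered regions, since 100 orders shuffled within chromosomes gave at most 1 run. Lower depth of the active libraries would make runs low in that group, but 79.7% of the runs were low in the inactive libraries. This share largely follows from the regions used, since 2318 regions changed at least 4-fold were higher and 627 lower in the active line. It is thus no separate support. With libraries thinned to equal depth there were 63 runs, 12 low in the active and 51 low in the inactive line. Loss of the DNA in all cells of 1 line would leave only background signal. The median left in the lowest library of the low group was 7.59% (bootstrap interval 5.31 to 9.18), above the bound assumed for this test. Background was not measured, so the test cannot decide whether all DNA was lost. A median over the runs also says nothing on single runs. Loss in most cells may account for the 2.07% to 20.03% of signal that the runs kept, a range limited by their choice at a 4-fold change, and cannot be told apart from closed chromatin. Ribozyme activity as the biological difference of the design stays open and was not tested apart from line identity.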
